A study of Rattus norvegicus with 15 samples.

How the data were processed

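Gene expression was measured by RNA sequencing of total RNA from undifferentiated Odora cells, with 3 libraries in each of 5 groups. The groups were untreated controls, 100 µM zinc gluconate for 6, 12 or 24 h, and 200 µM for 6 h, per the labels. The labels number the libraries of each group 1 to 3 and do not say that these came from separate cultures, so p-values measure the spread between these samples, which may be technical. The values are read counts per gene, deposited by the authors as whole numbers without normalization. The submitters' processing notes name bcl2fastq, CASAVA 1.8, TopHat, DESeq and the rat genome build rn4, without their roles. The read counter, the annotation, the strand setting and the treatment of reads that match several genes are not given in the sources used here, so genes with near-identical copies and genes that overlap others may hold shared reads.

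Gene identifiers were matched to symbols through a table of rat RefSeq genes of assembly GRCr8, which was used for names only, and no coordinates are given because the builds differ. Of 16832 identifiers 16671 matched and 161 did not, and the unmatched ones held 0.510% to 0.681% of the counts per library and were kept. Counts were at 0 in every library for 2758 identifiers. Total counts were 10.3 to 35.2 M (mega) per library, at which 3 counts, taken as the detection floor, equal 0.0853 to 0.290 CPM. These floors cover counting error only.

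The test of each comparison was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3, robust fit, TMM normalization), fitted to all 15 libraries with group as the only factor. The filterByExpr rule removed 6257 genes and left 10575, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. An overall test compared all 5 groups. Gene lists were tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01, with adjustment over the lists, and again with an estimated correlation and with fry, which tests whether the genes of a list move one way on balance and does not compare the list with other genes. Calls of single list members were adjusted over all genes and also over the list alone.

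The design, the alternatives, the rule for naming genes and 26 gene lists were fixed before the data were examined. The rule names Mt1, Mt2A, Slc30a1, Hmox1, Hspa1a, Ddit3, Cdkn1a, Fos and Mki67 in each comparison with control and between doses. It adds the 6 highest and 6 lowest ratios (4 and 4 between times) among genes with an adjusted p under 0.05, a mean of at least 20 counts and no overlap between the groups, leaving out identifiers without a gene name. From each list that passed camera or had at least 3 called members it adds up to 3 members with the smallest adjusted p. Ldhb, Nppa, Mb, the 6 heart muscle genes of the summed level and the transfer RNA synthetase genes were named after their values were seen. Some genes that the rule names are not reported here. Lists needed at least 3 tested genes for a set test, which left 25. The metallothionein list had 2 tested genes, Mt1 and Mt2A, and was not tested as a set.

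The lists, with the genes tested, were zinc exporters (7), zinc importers (10), cytosolic heat shock (22), Nrf2 antioxidant targets (21), the ATF4 response (22), ER chaperones (18), p53 targets (19), apoptosis regulators (21), immediate early genes (24), NF-kB and inflammation (14), G2/M (22), S phase (22), proteasome (32), glycolysis (18), hypoxia (15), respiratory chain (52), cholesterol synthesis (19), autophagy and lysosome (26), iron handling (12), olfactory lineage (11), sustentacular and basal epithelium (3), glia (7), fibroblasts (14), macrophages and leukocytes (4) and cytosolic ribosomal proteins (56). Some genes stand in more than 1 list, such as Hmox1 (Nrf2 and iron) and Slc2a1 (glycolysis and hypoxia).

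The alternatives set in advance were DESeq2 1.42.0, DESeq2 size factors in edgeR, library totals without a scaling factor, no filter, a filter of at least 50 counts in 3 libraries, a fit of the 6 libraries compared, the replicate number as a block, limma-voom, each replicate left out in turn, a log2 ratio of at least 1, and an adjusted p under 0.01 for overlaps. Alternatives added after seeing the data were fits without the libraries of the 24 h or the 200 µM label, sums of the matched libraries of these labels, thinning of all libraries to the smallest total, and a term for the 4 libraries with heart transcripts. Libraries with the same number deviated together in the comparison of the 24 h label with control, with correlations across genes of 0.176, 0.387 and 0.190 for numbers 1, 2 and 3. In every other comparison at least 1 number stayed under 0.1, so those numbers were not read as pairs. Between doses, though, all 6 libraries correlated best with their own number, as they did for the 24 h label. Library 1 of the 24 h label lay closest to library 3 of the 200 µM label, and its library 3 to library 1. The numbers may therefore not mark shared cultures, and the pairing for the 24 h label is uncertain.

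The methods were tested on simulated counts for 6 h at 100 µM against control, with known changes in 200 genes. Over 10421 genes edgeR recovered 83.6% of genes changed by a log2 ratio of 0.5 and 100% of those changed by 1 or 2, with 11 false calls. DESeq2 recovered 88.1% at 0.5 over 9612 genes, with 14 false calls, and limma-voom 86.6%, with 13. In the same simulation camera found a raised list of 34 genes and called 0 of 20 random lists, and the estimated correlation and fry also called 0 of these. The simulated genes were drawn independently. In the data the estimated correlation at 6 h was 0.485 for the ATF4 list and 0.671 for ribosomal protein genes. The simulation therefore does not test false list calls among genes that vary together. The first version of the simulation put no change into the counts and was corrected, and the simulation of unchanged groups against shared controls was redone with simulated controls after its first version had left out their error. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.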

Results

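RNA was sequenced from Odora cells, a rat cell line derived from olfactory tissue and labelled as olfactory neurons, after exposure to zinc gluconate, a zinc salt. The 15 libraries formed 5 groups of 3: untreated control cells, cells given 100 µM zinc gluconate for 6, 12 or 24 h, and cells given 200 µM for 6 h. The labels give no time for the controls. Total counts, in megacounts (M), were 23.7, 28.0 and 25.9 M in the controls and 35.2, 10.3 and 12.2 M after 6 h at 100 µM. They were 11.7 to 13.2 M after 12 h, 16.4 to 21.2 M under the 24 h label and 13.7 to 17.2 M under the 200 µM label. Changes are given as log2 ratios ± standard error, from 3 libraries per group, and levels as mean CPM (library totals scaled by TMM) ± SD (n = 3).

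Libraries labelled 24 h at 100 µM and those labelled 6 h at 200 µM lay next to each other in pairs. Between the counts of matched libraries the chi-square per degree of freedom was 1.39 to 1.46, against 3.67 or more between any libraries that shared either of these labels and 3.69 or more within the other groups. A direct edgeR comparison of both labels called 0 of 10575 genes, with 69 genes at an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0. Among genes over 50 CPM no log2 difference exceeded 0.16. Both labels are therefore described together as they stand, and differences that rest on the dose or on the 24 h time carry this doubt.

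**Figure D1:**
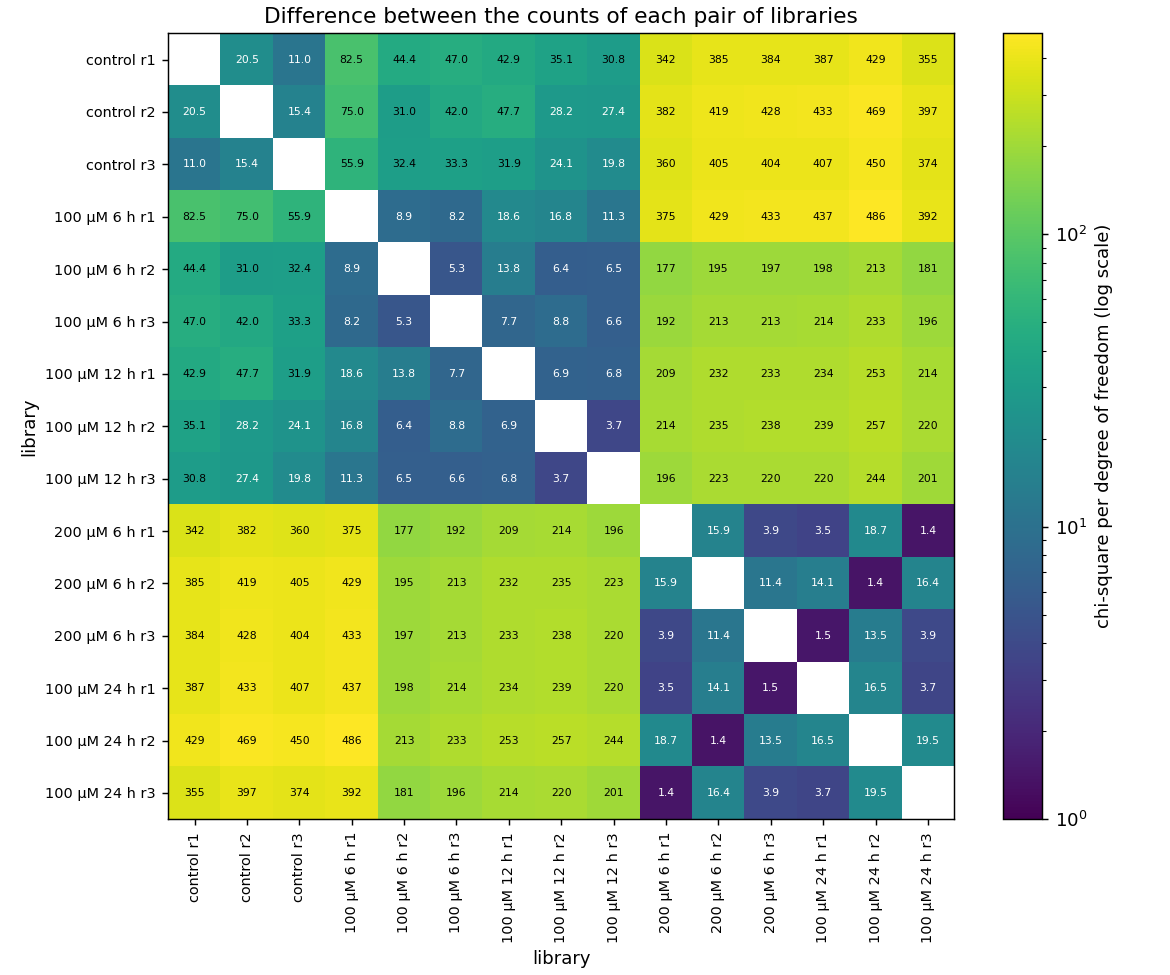
Chi-square per degree of freedom between the counts of each pair of the 15 libraries (library against library, colour scale as drawn). The 3 matched pairs between the 24 h label at 100 µM and the 6 h label at 200 µM lie at 1.39 to 1.46, below every pair that shares a label.

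Heart muscle transcripts also set some libraries apart. The summed level of Myh6, Myh7, Actc1, Myl2, Myl3 and Mybpc3, genes of the contractile apparatus of heart muscle, was 106, 26.7 and 107 CPM in the controls and 49.4 CPM in replicate 1 of 6 h at 100 µM. In the other 11 libraries it was 0.156 to 0.608 CPM. These 4 libraries are here called the heart-transcript libraries, and a model with a term for them, chosen after seeing the data, is given beside the counts of changed or shared genes that it moves by more than 1.5 times. All controls carry this term, so it is estimated only from replicate 1 of 6 h at 100 µM against the other libraries of that group.

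**Figure D2:**
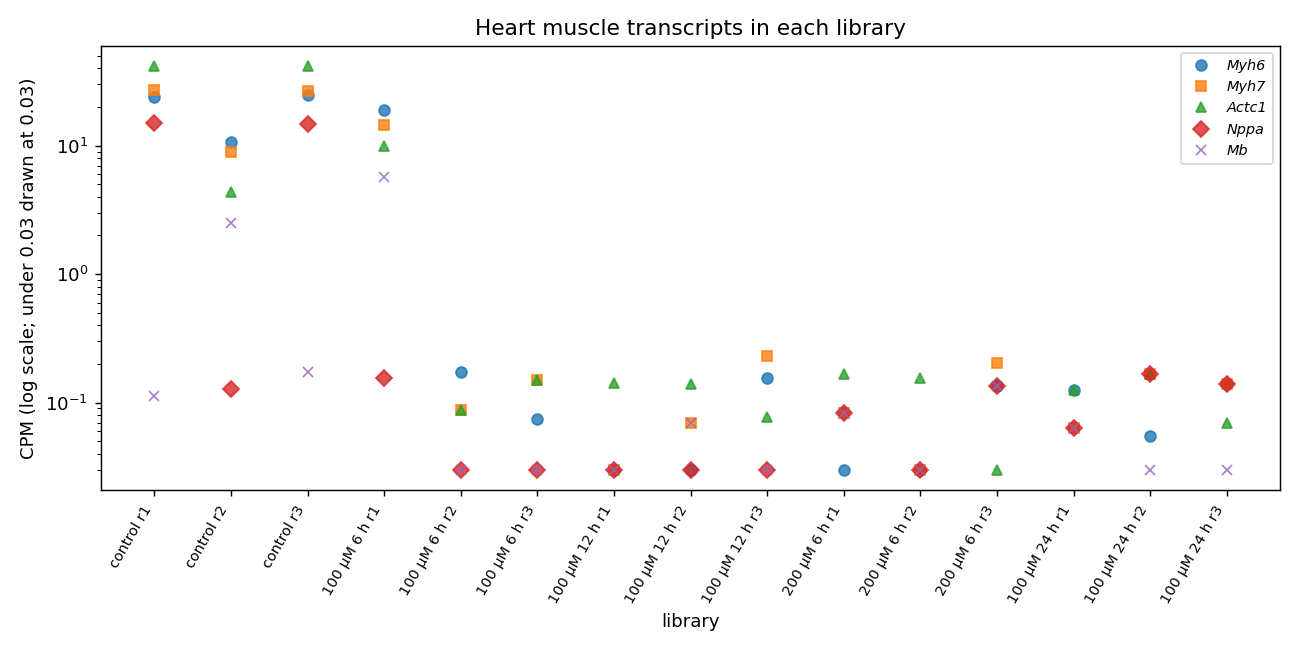
Level of the heart muscle genes Myh6, Myh7, Actc1, Nppa and Mb in each of the 15 libraries (CPM, log scale, values under 0.03 drawn at 0.03). For Myh6, Myh7 and Actc1 the 3 controls and replicate 1 of 6 h at 100 µM stand above the other 11 libraries, while Nppa is high in controls 1 and 3 and Mb in control 2 and in replicate 1 of 6 h.

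After 6 h at 100 µM, metallothionein genes and a zinc exporter gene rose against control. Mt1, a metallothionein that binds zinc in the cytosol, rose 31.6-fold, from 44.9 ± 7.03 to 1419 ± 71.7 CPM (log2 4.98 ± 0.17). Mt2A, another metallothionein, rose 15.4-fold (3.94 ± 0.13), and Slc30a1, a zinc exporter of the plasma membrane, rose by 2.0 ± 0.09. Hmox1, the haem-degrading enzyme haem oxygenase 1, rose 20.2-fold (4.34 ± 0.12), and the aldo-keto reductases Akr1b10, Akr1b7 and Akr1b8 rose by 2.66 ± 0.11, 2.59 ± 0.12 and 2.50 ± 0.11. The largest falls named by the rule were in Inhbe (-3.61 ± 0.42), which encodes an inhibin subunit, Angptl8 (-3.02 ± 0.40), a regulator of lipoprotein lipase, and Casp4 (-2.74 ± 0.21), an inflammatory caspase. Others were Cth (-2.54 ± 0.23), an enzyme of cysteine synthesis, and Extl1 (-2.28 ± 0.18), a glycosyltransferase. Cox6a2, the heart and muscle form of a cytochrome oxidase subunit, was also among them, at 0.389 ± 0.115 against 2.18 ± 1 CPM in the controls. The controls, which carried heart transcripts, were at 3.09, 1.11 and 2.36 CPM, so those transcripts may contribute to this fall. Replicate 1 of 6 h, which also carried them, was at 0.519 CPM, against 0.348 and 0.301 in replicates 2 and 3. Hspa1a, an inducible heat shock protein, rose by 1.00 ± 0.15, while Ddit3, a stress-induced transcription factor, fell (-0.73 ± 0.13). Cdkn1a, a cyclin-dependent kinase inhibitor, changed by -0.41 ± 0.11 (adjusted p = 0.0131), a call that ended with the heart-transcript term (-0.44 ± 0.16, adjusted p = 0.096). It also ended without control replicate 1, which lowered the size of the change to -0.24 ± 0.09 (adjusted p = 0.0845), and without 6 h replicate 1 (-0.39 ± 0.13) or 2 (-0.36 ± 0.12). Fos (0.07 ± 0.15, adjusted p = 0.792), an immediate early transcription factor, and Mki67 (0.10 ± 0.09, adjusted p = 0.51), a proliferation marker, did not pass. Akr1b7, Akr1b8 and Akr1b10 are close paralogs, as are Mt1 and Mt2A, and Hspa1a has a near-identical copy, so their values may hold shared reads.

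Among the gene lists, antioxidant targets of Nrf2 rose and targets of ATF4 fell after 6 h. Of 21 Nrf2 targets 17 rose and 0 fell (18 and 1 adjusted over the list alone), including Nqo1 (0.94 ± 0.07), a quinone reductase, and Srxn1 (0.87 ± 0.07), which repairs oxidised peroxiredoxins (camera adjusted p = 8.76e-15, and 0.00825 with an estimated correlation). Of 22 genes of the ATF4 stress response 20 fell (21 adjusted over the list alone), with Asns, asparagine synthetase, at -1.94 ± 0.10, Vldlr, a lipoprotein receptor, at -1.57 ± 0.09, and Chac1, a glutathione-degrading enzyme, at -1.51 ± 0.09 (camera adjusted p = 4.19e-28, and 0.0494 with an estimated correlation). Glycolytic genes rose in 14 of 18 cases (14 adjusted over the list alone), among them the glucose transporter Slc2a1 (0.75 ± 0.08) and the phosphofructokinase Pfkl (0.67 ± 0.08). Hypoxia response genes rose in 8 of 15 cases and fell in 1 (8 and 1 adjusted over the list alone), with the carbonic anhydrase Car9 at 1.08 ± 0.11. Cholesterol synthesis genes rose in 9 of 19 (12 adjusted over the list alone), with Hsd17b7 at 1.13 ± 0.13. These camera calls (adjusted p = 1.38e-09, 6.87e-05 and 5.96e-07) were lost with an estimated correlation (adjusted p = 0.129, 0.0736 and 0.191). Heat shock genes rose in 8 of 22 cases and fell in 1 (10 and 2 adjusted over the list alone), with the chaperones Hsph1 at 0.85 ± 0.10 and Hspa8 at 0.54 ± 0.06 (camera adjusted p = 1.65e-04, 0.191 with an estimated correlation). Iron handling genes rose in 6 of 12 cases (6 higher and 1 lower adjusted over the list alone), including the ferritin subunits Ftl1 (0.64 ± 0.10) and Fth1 (0.59 ± 0.10). Proteasome genes rose in 3 of 32, including Psmd3 (0.44 ± 0.07). These lists had camera adjusted p = 2.45e-04 and 6.87e-05 (0.0801 and 0.425 with an estimated correlation). Ribosomal protein genes fell in 6 of 56 cases (2 adjusted over the list alone), for example Rps6 at -0.32 ± 0.07 (camera adjusted p = 6.37e-04, 0.704 with an estimated correlation).

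The p53 target, lysosome and olfactory lineage lists passed camera at 6 h only narrowly (adjusted p = 0.0329, 0.0369 and 0.0441) and not with an estimated correlation (adjusted p = 0.425, 0.544 and 0.152). Of the p53 targets 1 rose and 5 fell (1 and 6 adjusted over the list alone), including Gadd45a (-1.07 ± 0.14), a DNA damage response gene. The list call ended without control replicate 1 (adjusted p = 0.0961), 6 h replicate 1 (0.0688) or 6 h replicate 2 (0.0657). Among lysosome genes 5 of 26 fell (6 adjusted over the list alone). The list call was lost without control replicate 2 (adjusted p = 0.115) or 6 h replicate 3 (0.128) and with the heart-transcript term (0.0652). Olfactory lineage markers rose in 4 of 11 cases and fell in 1, the G protein subunit Gng8 (-0.84 ± 0.15), with 7 and 1 adjusted over the list alone. That list call was lost without control replicate 2 (adjusted p = 0.0874) or 3 (0.0533), without 6 h replicate 2 (0.093) and with the heart-transcript term (0.197). No list call passed at 6 h for immediate early genes (6 higher and 3 lower of 24, 7 and 4 adjusted over the list alone, including the phosphatase gene Dusp5 at 0.75 ± 0.08) or NF-kB and inflammation genes (5 higher of 14, 6 adjusted over the list alone, including the chemokine gene Cxcl1 at 1.28 ± 0.12). The same held for G2/M genes (3 higher of 22) or S phase genes (1 higher and 4 lower of 22). Nor did one pass for apoptosis regulators (2 higher and 1 lower of 21), ER chaperones (2 lower of 18), the respiratory chain (2 higher of 52, 0 adjusted over the list alone), zinc exporters (1 higher of 7) or zinc importers (1 higher of 10). Immediate early genes did pass without control replicate 2 (0.0479). Markers of sustentacular and basal epithelium (1 of 3 lower), glia (1 of 7 lower), fibroblasts (1 higher and 1 lower of 14, 1 and 0 adjusted over the list alone) and leukocytes did not pass as lists either. The sustentacular list did pass without control replicate 1 (0.0272) or 3 (0.0288), 6 h replicate 2 (0.0353) or 3 (0.0421) or the 200 µM libraries (0.0347), and with the heart-transcript term (0.0354). Of 4 leukocyte markers 0 were called by edgeR, DESeq2 or limma-voom and 0 had an unadjusted p under 0.05. The median and the mean differed in sign for zinc importers (-0.01 and 0.04, camera upward), ER chaperones (0.07 and -0.01, upward) and apoptosis regulators (0.01 and -0.01, downward). With libraries scaled by their totals alone the medians of zinc exporters and apoptosis regulators turned from 0.01 and 0.01 to -0.02 and -0.02.

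In edgeR's quasi-likelihood test 1819 of 10575 genes changed after 6 h, 962 higher and 857 lower, and 140 of them by a log2 ratio of at least 1. The count was 1026 without control replicate 1, 1204 without 6 h replicate 1, 1210 without 6 h replicate 3 and 933 with the heart-transcript term. The share of higher genes was 52.9%, or 42.1% when libraries were scaled by their totals alone.

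**Figure D3:**
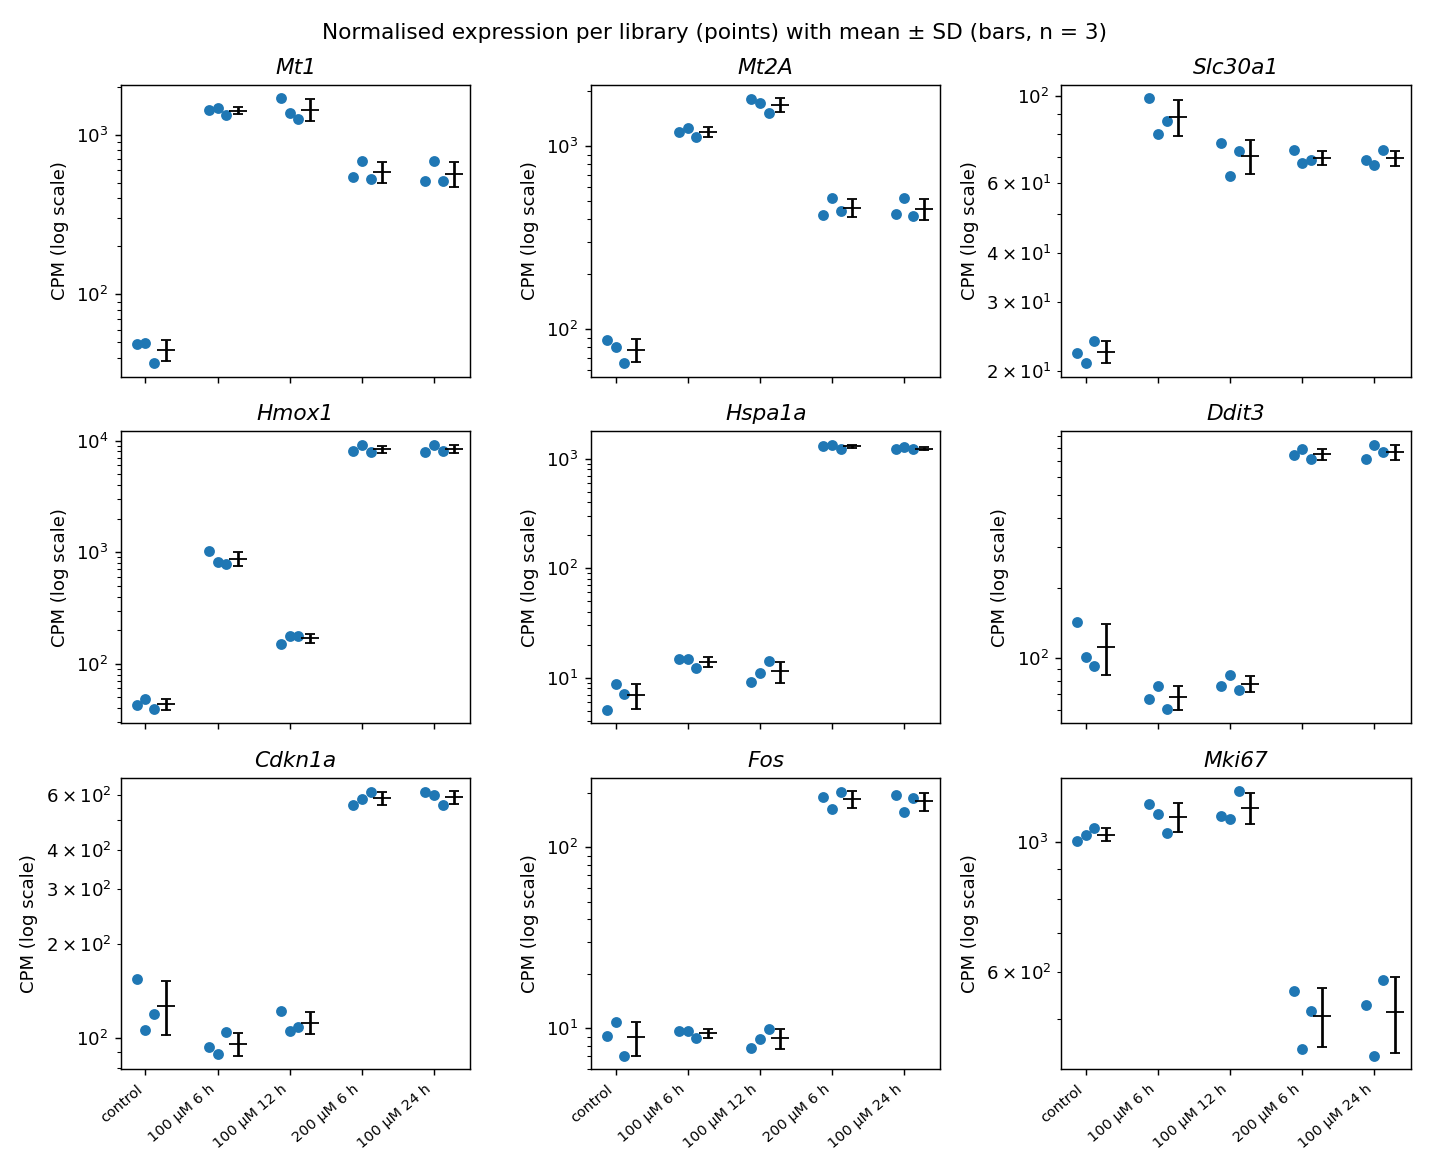
Normalised level (CPM, log scale) of single genes in each library (points), with mean ± SD per group (bars, n = 3). Mt1 and Hmox1 lie above the controls in all 4 zinc groups, and Hmox1 is lower after 12 h than after 6 h at 100 µM.

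After 12 h at 100 µM metallothionein and Hmox1 transcripts were again above control. Mt1 rose 32-fold against control (5.00 ± 0.17), Mt2A 21.7-fold (4.44 ± 0.13), Slc30a1 by 1.66 ± 0.09 and Hmox1 by 1.96 ± 0.11. The aldo-keto reductase genes Akr1b10, Akr1b7 and Akr1b8 rose by 2.21 ± 0.11, 2.16 ± 0.12 and 2.11 ± 0.11. Hspa1a (0.70 ± 0.17, adjusted p = 0.018) and Ddit3 (-0.53 ± 0.13, adjusted p = 0.0236) passed in the model of all 15 libraries. With the heart-transcript term they lay at 0.84 ± 0.27 and -0.56 ± 0.24 and did not pass (adjusted p = 0.246 and 0.393), nor did they in a fit of the 6 libraries alone (0.69 ± 0.20 and -0.54 ± 0.17, adjusted p = 0.073 and 0.118). Both calls were also lost without control replicate 1 (0.52 ± 0.14 and -0.31 ± 0.09) or 12 h replicate 3 (0.53 ± 0.17 and -0.48 ± 0.15). The Ddit3 call was lost without 12 h replicate 1 (-0.52 ± 0.15), and that of Hspa1a after thinning all libraries to the smallest total (0.62 ± 0.22, adjusted p = 0.134). Cdkn1a (-0.18 ± 0.11), Fos (-0.03 ± 0.16) and Mki67 (0.15 ± 0.09) did not pass (adjusted p = 0.369, 0.949 and 0.409). The genes with the lowest ratios after 12 h were Mybpc3, Myh6, Actc1, Myh7, Myl2 and Acta1, a skeletal muscle actin gene. The first 5 are among the heart muscle genes described above, and all 6 lost their call with the heart-transcript term.

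Of the 21 Nrf2 targets 13 rose and 3 fell after 12 h (15 and 3 adjusted over the list alone), with Nqo1 at 0.93 ± 0.07 (camera adjusted p = 8.32e-12, 0.0217 with an estimated correlation). ATF4 response genes fell in 17 of 22 cases (20 adjusted over the list alone), with Vldlr at -0.93 ± 0.09, Asns at -0.97 ± 0.10 and Chac1 at -0.75 ± 0.09 (camera adjusted p = 6.10e-23, 0.0738 with an estimated correlation). Cholesterol synthesis genes rose in 11 of 19 cases (19 adjusted over the list alone). Glycolytic genes rose in 13 of 18 (13 higher and 1 lower adjusted over the list alone), with lactate dehydrogenase Ldha at 0.66 ± 0.09. Their camera adjusted p-values were 5.69e-15 and 2.84e-12 (both 0.0738 with an estimated correlation). The median glycolytic change was 0.45 and the mean 0.006. The mean was lowered by Ldhb, another lactate dehydrogenase gene, which was at 0.769 ± 0.524 CPM in the controls and at 0 in all 3 libraries of 12 h and did not pass (adjusted p = 0.119).

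Other lists passed camera upward after 12 h without holding with an estimated correlation. They were heat shock (6 of 22 higher, 7 adjusted over the list alone, Hsph1 at 0.78 ± 0.10), hypoxia (6 higher and 1 lower of 15, Car9 at 1.21 ± 0.11) and iron handling (3 of 12 higher, 5 adjusted over the list alone). Their camera adjusted p-values were 1.18e-05, 0.00111 and 3.61e-04, and 0.132, 0.0881 and 0.0738 with an estimated correlation. The proteasome (5 of 32 higher, 12 adjusted over the list alone) and G2/M lists (2 of 22 higher, 3 adjusted over the list alone) passed with camera adjusted p = 1.06e-08 and 4.78e-06 (0.197 and 0.166 with an estimated correlation). Respiratory chain genes (1 of 52 higher) passed with adjusted p = 0.00385 (0.558 with an estimated correlation), 0 members called adjusted over the list alone, a list call lost without control replicate 2 (0.0677) or 12 h replicate 1 (0.185). Olfactory lineage markers (2 higher and 1 lower of 11, 3 and 1 adjusted over the list alone) passed with adjusted p = 0.0134 (0.0738 with an estimated correlation, 0.666 with the heart-transcript term). Lysosome genes passed downward (4 of 26 lower, 5 adjusted over the list alone, camera adjusted p = 4.92e-04, 0.235 with an estimated correlation). No call was made for ER chaperones (2 higher and 2 lower), p53 targets (1 and 1), immediate early genes (1 and 2) or S phase genes (1 and 1). Nor was one made for NF-kB genes, zinc exporters, zinc importers or fibroblast markers, each with 1 gene higher. Adjusted over the list alone the counts were 4 and 2 for ER chaperones, 1 and 2 for p53 targets, 2 and 1 for S phase genes, 2 higher for NF-kB genes and 1 and 2 for fibroblast markers. The fibroblast list did pass without control replicate 1 (0.00943), 12 h replicate 2 (0.0353) or 12 h replicate 3 (0.0398) and with the heart-transcript term (0.00206). With that term ER chaperones (0.013) and sustentacular markers (0.012) passed too. In fits without that term p53 targets passed without control replicate 2 (0.0234), S phase genes without control replicate 1 (0.0297) and ribosomal protein genes without 12 h replicate 1 (0.00655, downward) or 3 (0.0447, upward). Apoptosis regulators, ribosomal protein genes and markers of sustentacular cells, glia and leukocytes had 0 members called by edgeR and did not pass camera either. At an unadjusted p under 0.05 they held 3, 1, 1, 1 and 0 genes, and limma-voom called 0 of them and DESeq2 1 ribosomal gene. The median of zinc exporters (-0.02) differed in sign from their mean (0.20) and from camera's upward direction, and for ribosomal genes a median and mean of 0.004 stood against a downward direction. With libraries scaled by their totals alone the medians of NF-kB, S phase and ribosomal genes turned from 0.04, 0.04 and 0.004 to -0.01, -0.01 and -0.04.

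In edgeR's quasi-likelihood test 669 genes changed after 12 h, 355 higher and 314 lower, 61 of them by a log2 ratio of at least 1. The share of higher genes was 53.1%, or 34.0% with libraries scaled by their totals alone. The count was 271 without 12 h replicate 1, 438 without replicate 2, 401 without replicate 3, 286 without control replicate 1 and 50 with the heart-transcript term, which raised the median standard error from 0.094 to 0.167. That term also moved the estimates, and the log2 changes with and without it correlated at 0.612 across all tested genes.

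The comparison of 12 h with 6 h at 100 µM asks which levels moved between these times. Hmox1 was lower after 12 h by -2.38 ± 0.11, and with it Gclm, a subunit of the enzyme that starts glutathione synthesis (-0.72 ± 0.09), and Srxn1 (-0.56 ± 0.07). Genes higher after 12 h included the aminotransferase gene Gpt2 (1.10 ± 0.09), Asns (0.96 ± 0.10), Psat1 (0.69 ± 0.07), an enzyme of serine synthesis, and Mthfd2 (0.73 ± 0.08), a mitochondrial folate enzyme. The pseudokinase gene Trib3 was higher by 1.02 ± 0.15, and Ptgs2, a cyclooxygenase gene, lower (-0.61 ± 0.09). Of the ATF4 list 13 of 22 genes were higher (16 adjusted over the list alone, camera adjusted p = 6.91e-27, 0.0445 with an estimated correlation). Of the Nrf2 list 5 of 21 were lower (8 adjusted over the list alone, 3.11e-10 and 0.0331). S phase genes passed as a list (0.00306, 0.0445 with an estimated correlation) with 0 members called by edgeR (1 adjusted over the list alone, 3 at an unadjusted p under 0.05, 1 with DESeq2 and 0 with limma-voom). Immediate early, NF-kB, hypoxia and iron handling genes passed camera downward with 2, 2, 1 and 1 members lower. Adjusted over the list alone 6, 2, 3 and 2 were lower and 1 immediate early gene higher. G2/M and ribosomal protein genes passed upward with 0 members called by edgeR, DESeq2 or limma-voom, and 7 and 2 at an unadjusted p under 0.05. These 6 calls were lost with an estimated correlation (adjusted p = 0.333, 0.333, 0.333, 0.333, 0.514 and 0.543). The NF-kB call was also lost without 6 h replicate 3 (0.112) or 12 h replicate 1 (0.174). The hypoxia call was lost without 6 h replicate 1 (0.209), 12 h replicate 2 (0.0877) or 12 h replicate 3 (0.117), with the heart-transcript term (0.206) and without the libraries of the 24 h label (0.0533). Other lists did not pass. Of these, respiratory chain genes did without 6 h replicate 1 (0.031) or 3 (0.0106), 12 h replicate 3 (2.74e-04) or the libraries of the 24 h label (0.048), and with the heart-transcript term (0.0307). ER chaperones and fibroblast markers did without 6 h replicate 1 (0.0322 and 0.0388) and with that term (0.0321 and 0.0395). With 1 library left out p53 targets (6 h replicate 3, 0.0105, and 12 h replicate 2, 0.0183), heat shock genes (6 h replicate 2, 0.0439, and 12 h replicate 1, 0.033), cholesterol synthesis (12 h replicate 2, 0.0183) and glycolysis (12 h replicate 1, 0.0137) passed too. The median and mean differed in sign for heat shock (0.01 and -0.04) and glycolysis (0.02 and -0.34), both downward by camera, and for apoptosis regulators (0.02 and -0.004, downward) and olfactory markers (-0.009 and 0.001, upward). The heat shock and ER chaperone medians (0.01 and 0.01) turned to -0.001 and -0.003 with libraries scaled by their totals alone.

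Between 12 h and 6 h 103 genes differed, 51 higher and 52 lower after 12 h, and 5 of them by a log2 ratio of at least 1. The count was 50 without 6 h replicate 1, 68 without 6 h replicate 3, 58 without 12 h replicate 2, 51 with the heart-transcript term, 200 with DESeq2 and 223 in a fit of the 6 libraries alone.

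In the libraries labelled 200 µM for 6 h and in those labelled 100 µM for 24 h, stress genes rose far above control. Values are given for the 200 µM label first and the 24 h label next. Hmox1 reached 8382 ± 657 and 8414 ± 712 CPM, a rise of 7.60 ± 0.14 and 7.60 ± 0.14, and Hspa1a reached 1290 ± 52.8 and 1234 ± 28.5 CPM (7.52 ± 0.16 and 7.45 ± 0.16). Sorl1, a sorting receptor gene, rose by 6.41 ± 0.33 and 6.44 ± 0.32, and Cd300lb, an immune receptor gene, by 7.35 ± 0.50 and 7.43 ± 0.49. The same rule named Ankrd34b (6.79 ± 0.51 and 6.90 ± 0.50), Btnl7 under the 200 µM label (6.20 ± 0.53) and Zfand2a, a heat- and arsenite-inducible gene, under the 24 h label (6.19 ± 0.13). Mt1 rose by 3.70 ± 0.16 and 3.67 ± 0.16, Mt2A by 2.58 ± 0.12 and 2.55 ± 0.12, and Slc30a1 by 1.64 ± 0.09 and 1.64 ± 0.09. Fos (4.36 ± 0.13 and 4.32 ± 0.13), Ddit3 (2.74 ± 0.13 and 2.77 ± 0.13) and Cdkn1a (2.21 ± 0.11 and 2.22 ± 0.11) rose, and Mki67 fell (-1.02 ± 0.10 and -1.0 ± 0.10). The 6 lowest ratios under each label belonged to the heart muscle genes Myh6, Myh7, Actc1, Myl2, Myl3 and Mybpc3, and each lost its call with the heart-transcript term.

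Chaperone genes of the cytosol and of the ER rose under both labels. Heat shock genes rose in 20 of 22 cases under each label, with Hsph1 at 5.83 ± 0.12 and 5.84 ± 0.12 and the co-chaperone Dnajb1 at 3.12 ± 0.08 and 3.11 ± 0.08 (camera adjusted p = 7.36e-15 and 1.89e-14, 0.0283 and 0.0292 with an estimated correlation). Nrf2 targets rose in 19 of 21 cases and fell in 1 under each label, with Srxn1 at 3.85 ± 0.08 and 3.83 ± 0.08 and the thioredoxin reductase Txnrd1 at 1.58 ± 0.07 and 1.57 ± 0.07 (camera adjusted p = 1.14e-09 and 2.42e-09, 0.0283 and 0.0292 with an estimated correlation). ER chaperone genes rose in 17 of 18 cases and fell in 1, with Hspa5, the main ER chaperone, at 3.23 ± 0.07 and 3.23 ± 0.07 (camera adjusted p = 6.26e-10 and 1.18e-09, 0.0511 and 0.0592 with an estimated correlation). Immediate early genes rose in 19 of 24 cases and fell in 3 and 4, with Fosb at 5.42 ± 0.14 and 5.41 ± 0.14 and Jun at 2.41 ± 0.07 and 2.39 ± 0.07, both transcription factors (camera adjusted p = 3.49e-10 and 1.02e-09, 0.0511 and 0.0603 with an estimated correlation). These counts were the same adjusted over the list alone, except 4 immediate early genes lower under the 200 µM label.

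ATF4 response genes rose in 15 and fell in 6 of 22 cases under each label. Sesn2, a stress-induced regulator of growth signalling, was at 3.46 ± 0.07 and 3.39 ± 0.07, Ddit4, another such regulator, at 3.59 ± 0.09 and 3.55 ± 0.09 and Chac1 at 2.68 ± 0.09 and 2.68 ± 0.09 (camera adjusted p = 2.60e-04 and 3.25e-04, 0.378 and 0.388 with an estimated correlation). Cholesterol synthesis genes rose in 18 of 19 cases. Glycolytic genes rose in 14 and fell in 1 of 18, with Slc2a1 at 2.60 ± 0.09 and 2.57 ± 0.09 and the hexokinase Hk2 at 1.58 ± 0.12 and 1.57 ± 0.12. Their camera adjusted p-values were 1.07e-10 and 1.46e-10 for cholesterol (0.12 and 0.125 with an estimated correlation) and 3.47e-05 and 4.99e-05 for glycolysis (0.303 and 0.317). G2/M genes fell in 12 and rose in 4 of 22 cases, with Plk1, a mitotic kinase, at -1.17 ± 0.10 and -1.17 ± 0.10, and with the cyclin gene Ccnf higher (1.31 ± 0.07 and 1.36 ± 0.07). Camera gave adjusted p = 0.0171 and 0.0345 for this list (0.432 and 0.458 with an estimated correlation, 0.0575 and 0.0853 with the heart-transcript term). Under the 24 h label the call was lost without control replicate 3 (0.0567) or 24 h replicate 1 (0.0712). NF-kB genes rose in 9 and fell in 2 of 14 cases under the 200 µM label (camera adjusted p = 0.0419, 0.303 with an estimated correlation, 0.0657 without control replicate 1, 0.0541 without 200 µM replicate 2 and 0.0673 with the heart-transcript term). Under the 24 h label 9 were higher and 3 lower, and the list did not pass (0.0514), though it did without control replicate 2 (0.0473) or 24 h replicate 3 (0.0235), without the 200 µM libraries (0.0419) and with matched libraries summed (0.04).

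Proteasome genes were higher in 28 of 32 cases under each label, with Psmd8 at 0.69 ± 0.07 and 0.67 ± 0.07, but the list median of 0.36 and 0.36 turned to -0.02 and -0.02 when libraries were scaled by their totals alone. The same turn was seen for ribosomal protein genes (41 and 40 of 56 higher, 41 and 46 adjusted over the list alone, median 0.25 and 0.26, against -0.12 and -0.11) and respiratory chain genes (30 and 32 higher and 3 lower under each label of 52, 32 and 34 higher and 3 lower adjusted over the list alone, median 0.19 and 0.21, against -0.18 and -0.17). Lysosome and autophagy genes (16 and 15 higher and 1 lower of 26, median 0.26 and 0.28) turned to -0.12 and -0.09, although the autophagy receptor gene Sqstm1 was at 1.91 ± 0.09 and 1.92 ± 0.09. Hypoxia response genes (10 higher and 1 lower of 15, median 0.35 and 0.37) turned to -0.02 and -0.01. Camera adjusted p-values under the 200 µM label were 1.07e-06, 9.98e-06, 9.20e-04, 4.30e-04 and 0.00336 for these lists in the order given, and 0.303, 0.464, 0.464, 0.303 and 0.164 with an estimated correlation. Under the 24 h label they were 1.02e-06, 1.09e-05, 0.00103, 3.25e-04 and 0.0018, and 0.333, 0.458, 0.458, 0.317 and 0.129 with an estimated correlation.

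Lists without a camera call under either label in the model of all 15 libraries still held changed genes. Among p53 targets 8 rose under each label and 6 and 7 fell, with the antiproliferative gene Btg2 at 4.20 ± 0.15 and 4.22 ± 0.15. Apoptosis regulators were higher in 8 and 7 and lower in 4 cases, with Bcl2l1, which encodes an inhibitor of apoptosis, at 1.16 ± 0.08 and 1.14 ± 0.08. S phase genes were higher in 4 and lower in 9 and 10 cases, with Cdca7 at -1.47 ± 0.06 and -1.38 ± 0.06. Zinc exporters (4 higher, 1 lower) and importers (1 higher, 4 lower), iron handling genes (7 higher, 2 lower) and olfactory lineage markers (4 higher, 2 lower) had these counts under each label, with the ferritin gene Ftl1 at 1.5 ± 0.10 and 1.49 ± 0.10 and the olfactory transcription factor gene Ebf2 at 1.11 ± 0.15 and 1.13 ± 0.14. With the replicate number as a block, which may pair the libraries for the 24 h label, the iron handling list passed under that label (0.0412). It also passed with the heart-transcript term (0.0359 and 0.0475), and under the 200 µM label without control replicate 3 (0.0473), 200 µM replicate 3 (0.0356) or the 24 h libraries (0.0489). Fibroblast markers went both ways (5 and 4 higher, 5 lower), with the growth factor receptor gene Pdgfra at -2.01 ± 0.27 and -2.02 ± 0.26 and the actin-binding protein gene Tagln at 1.70 ± 0.28 and 1.74 ± 0.28. Sustentacular markers were lower in 1 and 2 of 3, glial markers in 1 of 7, and leukocyte markers were higher in 1 and lower in 1 of 4. Adjusted over the list alone 0 leukocyte markers were lower under the 200 µM label, and 2 zinc exporters lower, 11 S phase genes lower and 5 fibroblast markers higher under the 24 h label. Scaling by library totals alone turned the medians of zinc exporters from 0.25 and 0.25 to -0.12 and -0.13 and of p53 targets from 0.02 and 0.03 to -0.36 and -0.35. It turned those of apoptosis regulators from 0.12 and 0.14 to -0.26 and -0.24. It turned those of iron handling genes from 0.31 and 0.28 to -0.06 and -0.09. The medians of olfactory markers (0.25 and 0.17) turned to -0.12 and -0.20 and those of leukocyte markers from 0.18 and 0.21 to -0.20 and -0.17. Under the 200 µM label the glial median (0.08) turned to -0.30 and differed in sign from the mean (-0.08) and from camera's downward direction.

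**Figure D4:**
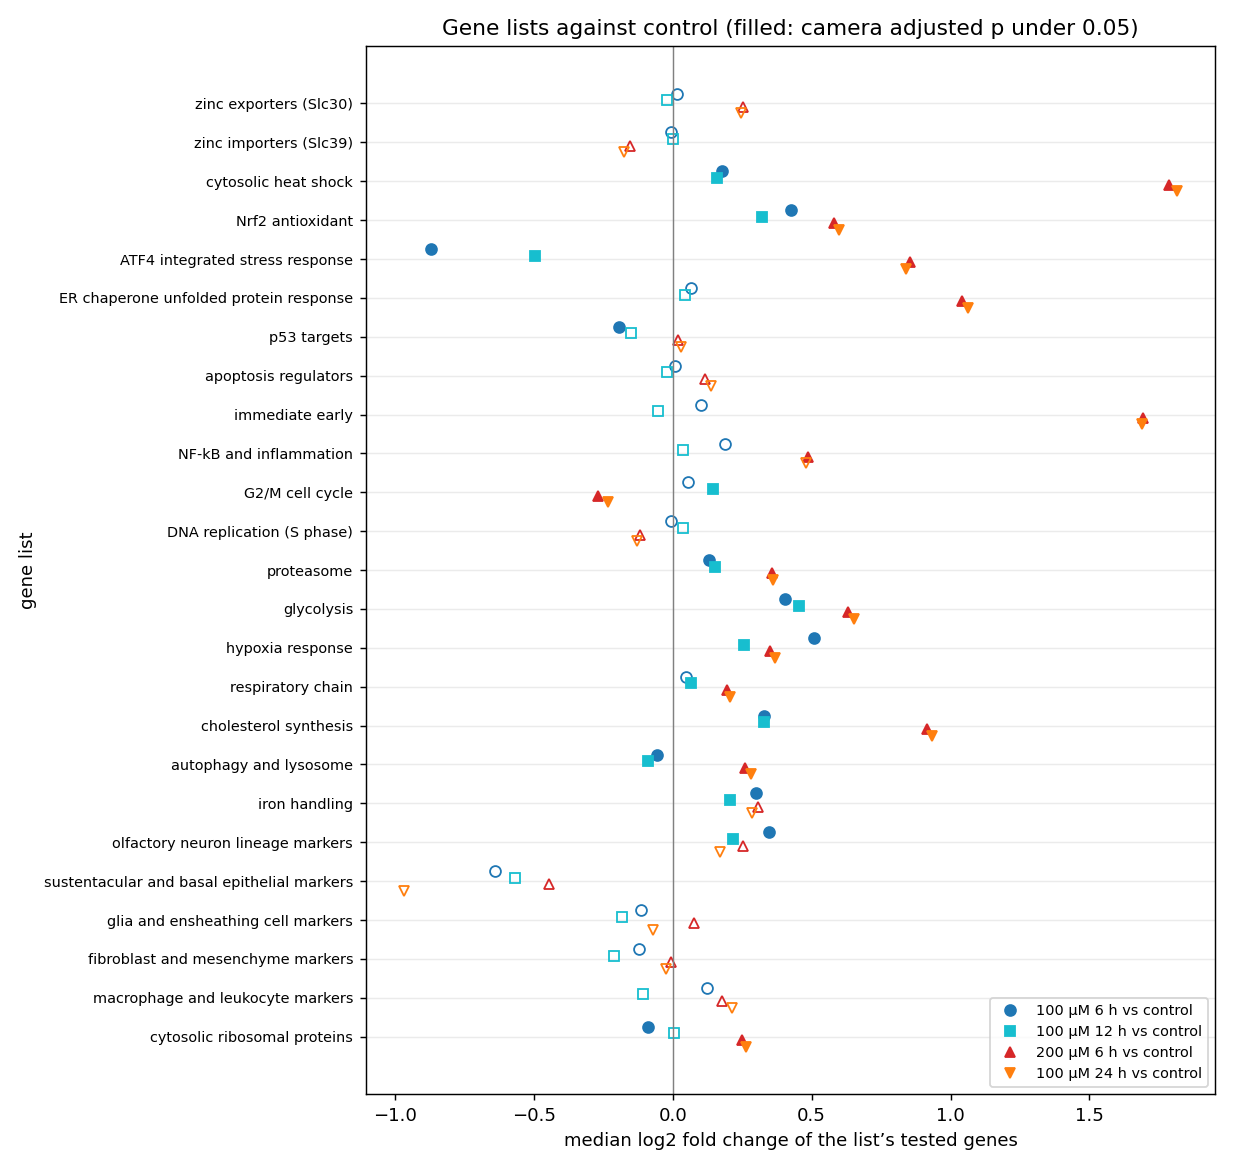
Median log2 change of the tested genes of each list (horizontal axis) against control for the 4 zinc groups, with filled symbols where the camera adjusted p was under 0.05. The ATF4 list lies at -0.87 and -0.50 after 6 and 12 h at 100 µM and at 0.85 and 0.84 under the 200 µM and 24 h labels, and the medians of the proteasome, hypoxia, respiratory chain, autophagy and ribosomal lists under those labels fall below 0 when libraries are scaled by their totals alone.

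Against control 6402 genes changed under the 200 µM label (3108 higher, 3294 lower) and 6449 under the 24 h label (3143 higher, 3306 lower), and 1299 and 1281 of them by a log2 ratio of at least 1. With libraries scaled by their totals alone the median of all genes lay at -0.40 under each label, against -0.02 with TMM, and the share of higher genes went from 48.5% and 48.7% to 16% and 16.2%. With the heart-transcript term 3898 and 3880 genes changed.

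The comparison of 200 µM with 100 µM at 6 h addresses the dose, as far as the 200 µM label holds. Metallothionein transcripts were lower under the 200 µM label than after 100 µM, Mt1 by -1.28 ± 0.14 and Mt2A by -1.37 ± 0.11, and Slc30a1 was lower by -0.35 ± 0.08. Hspa1a was higher by 6.52 ± 0.15, Fos by 4.29 ± 0.14, Ddit3 by 3.47 ± 0.14, Hmox1 by 3.26 ± 0.11 and Cdkn1a by 2.61 ± 0.11, and Mki67 was lower (-1.12 ± 0.10). Stmn4, a stathmin gene, had the highest ratio (6.91 ± 0.47), and Nppb, which encodes a natriuretic peptide, was at 6.19 ± 0.97. Among the lowest were Pcdh18, a protocadherin gene (-3.43 ± 0.25), Hyal2, a hyaluronidase gene (-3.21 ± 0.11), Cyp1b1, a cytochrome P450 gene (-3.14 ± 0.13), and Emilin1, which encodes a matrix protein (-3.07 ± 0.11). ATF4 response genes were higher in 21 and lower in 1 of 22 cases, with Sesn2 at 4.53 ± 0.08 and Chac1 at 4.19 ± 0.10 (camera adjusted p = 3.85e-16, 0.12 with an estimated correlation). Heat shock genes were higher in 20 of 22 cases (21 adjusted over the list alone, 7.80e-17 and 0.0336) and ER chaperone genes in 17 of 18 (1.07e-11 and 0.0469). Immediate early genes were higher in 19 of 24, with 2 lower (1.07e-11 and 0.0469). Cholesterol synthesis (17 of 19 higher), autophagy (19 of 26 higher, 21 adjusted over the list alone) and G2/M genes (14 lower and 2 higher of 22) passed camera (adjusted p = 5.00e-09, 7.75e-07 and 0.00182) but not with an estimated correlation (adjusted p = 0.149, 0.149 and 0.509).

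Nrf2 targets (12 higher and 1 lower of 21, 2 lower adjusted over the list alone), proteasome genes (16 of 32 higher), respiratory chain genes (29 higher and 2 lower of 52, 30 higher adjusted over the list alone) and ribosomal protein genes (53 of 56 higher, 54 adjusted over the list alone) also passed camera upward in the dose comparison (adjusted p = 3.48e-04, 0.00104, 0.00227 and 1.10e-10). Their medians of 0.21, 0.16, 0.20 and 0.33 turned to -0.14, -0.18, -0.15 and -0.01 with libraries scaled by their totals alone. With an estimated correlation their adjusted p-values were 0.143, 0.517, 0.61 and 0.512. The remaining lists did not pass, though p53 targets did without 6 h replicate 3 (0.0454) or 200 µM replicate 1 (0.0473), and glycolysis without the latter (0.0473). The median and mean differed in sign for glycolysis (0.21 and -0.07, upward by camera), olfactory markers (-0.13 and 0.002, downward) and fibroblast markers (0.008 and -0.21, upward).

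In all 5663 genes differed between the doses (2799 higher, 2864 lower at 200 µM), 1075 of them by a log2 ratio of at least 1. The share of higher genes was 49.4%, or 14.6% with libraries scaled by their totals alone, when the median of all genes lay at -0.35 (-0.008 with TMM).

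The libraries labelled 24 h were also compared with those of 12 h and of 6 h at 100 µM, which addresses time as far as the 24 h label holds. Hspa1a was higher than after 12 h by 6.76 ± 0.16 and than after 6 h by 6.45 ± 0.15, and Nppb by 7.17 ± 1.26 and 6.00 ± 0.98. Pcdh18 was lower by -3.21 ± 0.25 and -3.58 ± 0.24, and Dbr1, which encodes the RNA lariat debranching enzyme, by -3.34 ± 0.11 and -3.32 ± 0.11. Heat shock genes were higher in 20 of 22 cases in each comparison (21 against 6 h adjusted over the list alone, camera adjusted p = 3.58e-16 and 2.51e-16, 0.0411 and 0.0383 with an estimated correlation). ATF4 response genes were higher in 17 and 21 of 22 cases and lower in 2 and 1 (camera adjusted p = 1.41e-09 and 1.72e-15, 0.199 and 0.134 with an estimated correlation). ER chaperone genes were higher in 17 and 16 of 18, 17 and 17 adjusted over the list alone (6.62e-11 and 3.21e-11, 0.0575 and 0.054 with an estimated correlation). Against 12 h 5766 genes differed (2846 higher, 2920 lower), 1135 of them by a log2 ratio of at least 1. Against 6 h 5738 differed (2856 higher, 2882 lower), 1064 of them by that much. The share of higher genes was 49.4% and 49.8%, or 16.2% and 14.7% with libraries scaled by their totals alone, when the median of all genes lay at -0.34 and -0.35 (-0.008 and -0.006 with TMM).

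Genes called in more than 1 comparison with control mostly moved the same way. After 6 and 12 h at 100 µM 288 genes were higher in both and 265 lower in both, where independent lists would share 32.3 and 25.4. With the heart-transcript term, which left 933 and 50 calls, 34 were higher and 16 lower in both (1.67 and 0.625 for independent lists of those calls). After 6 h at 100 µM and under the 200 µM label 671 were higher in both and 501 lower in both (283 and 267 for independent lists), and 209 moved in opposite directions. With the term these numbers were 358 and 225 (92 and 79.2), and 61. After 12 h and under the 24 h label 261 were higher in both and 195 lower in both (106 and 98.2), and 91 moved in opposite directions. With the term they were 28 and 13 (6.08 and 3.01), and 2. Across 8783 genes, which are not independent replicates, the changes after 6 and 12 h correlated at 0.751 (covariance 0.0524), those after 6 h and under the 200 µM label at 0.420 (0.0815), and those after 12 h and under the 24 h label at 0.372 (0.0665). Unchanged groups simulated against the same controls gave a correlation of 0.471 with a covariance of 0.00611, and a median of 0 shared calls in 20 draws. The 3 controls cannot be split into parts of at least 2 libraries, so part of the excess may come from the shared controls. In all 4 comparisons 219 genes were higher and 160 lower, or 28 and 13 with the heart-transcript term and 83 and 69 at an adjusted p under 0.01. The 24 h and 200 µM labels may hold the same samples, so these 4 comparisons may not be separate. In the overall edgeR test 7022 of 10575 genes differed among the 5 groups.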

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

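The chi-square comparison of library pairs, the heart gene tests, the thinned counts and the ratio of the 12 h to the 6 h change were chosen only after the results were seen, while the differences between doses and times and the other splits of the libraries were planned.

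The groups given zinc differed from each other in direct tests, except the 200 µM and 24 h labels, between which 0 of 10575 genes differed. Between 200 µM and 100 µM at 6 h 5663 genes differed, between 12 h and 6 h 103, between the 24 h label and 12 h 5766 and between the 24 h label and 6 h 5738. In the dose comparison Mt1 differed by -1.28, Mt2A by -1.37, Slc30a1 by -0.35 and Mki67 by -1.12, against 3.26 for Hmox1, 6.52 for Hspa1a, 3.47 for Ddit3, 2.61 for Cdkn1a and 4.29 for Fos (log2, edgeR). Between 12 h and 6 h Hmox1 differed by -2.38 and Mt2A by 0.49 (adjusted p = 0.042). The Mt2A call was lost with the heart-transcript term (0.50 ± 0.13, adjusted p = 0.179), after thinning (0.48 ± 0.12, adjusted p = 0.068) and without any 1 of the 6 h libraries or 12 h replicate 1 or 2 (0.44 to 0.53). Between the 24 h label and 12 h Mt1 differed by -1.33, Mt2A by -1.88 and Mki67 by -1.15, against 5.64 for Hmox1, 6.76 for Hspa1a, 3.30 for Ddit3, 2.40 for Cdkn1a and 4.35 for Fos. Of the 10 splits of the 6 libraries of each comparison the real ones called 1758 genes for 6 h against control, 629 for 12 h, 6094 for the 24 h label, 6034 for the 200 µM label, 5409 between doses, 223 between 12 and 6 h, 5610 between the 24 h label and 12 h and 5521 between it and 6 h. The highest other split called 10 genes between 12 and 6 h and 0 in the rest, and 10 splits are too few for a share under 0.05. Over the 5 groups the real grouping (7022 genes) was the 1 of 61 groupings with as many calls, the highest other calling 0. These regroupings treat all libraries as separate samples, which is in doubt for the 24 h and 200 µM labels. They also do not tell which groups differ, so chance is not excluded by them.

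Each library labelled 24 h lay next to 1 library labelled 200 µM, 1 to 1, at a chi-square per degree of freedom of at most 1.46. Separate exposures with the same response are argued against by the pairs that share a label, none of which came below 3.67. The values are consistent with the same 3 samples standing under both labels, sequenced or prepared again, since the matched counts are not identical. The mean change under both labels correlated across genes with the change after 6 h at 100 µM at 0.418 and with that after 12 h at 0.377. If the samples are the same, which label is wrong stays open, because only the labels tell them apart. A real effect of 200 µM or of 24 h stays untested for the same reason.

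Heart muscle genes stood high in the 3 controls and in replicate 1 of 6 h at 100 µM, which are also the 4 deepest libraries. Of 18 other heart genes in the table, listed without regard to their values, 8 (44.4%) were higher in all 4 libraries than in the other 11, and among the 11 of them that were tested 6 were, against 0.785% of all genes tested, which is consistent with RNA or reads from heart muscle. The same heart RNA in all 4 is argued against by the ratio of Mb to Nppa, which differed 4842-fold between them. Mb had 3 and 5 counts in controls 1 and 3, against 398 and 426 for Nppa. In control 2 and 6 h replicate 1 Nppa had 4 and 6 counts, against 79 and 219 for Mb. The low counts lie near the floor of 3, so the size of the ratio is imprecise. Heart genes of the cells themselves, lowered by zinc, stay open. The explanation needs the 3 libraries of 6 h to lie together, and 4 of 6 genes differed over 10 times between them. Myl2 and Myl3 were at 0 in replicates 2 and 3, so their ratios to the floor (7.48 and 6.67) are lower limits. Whether these 2 genes differed over 10 times cannot be told. The summed level of the 6 genes differed 142-fold, a measure tried after that count had been seen. Like the single ratios, it rests on replicate 1 alone.

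Fewer genes changed after 12 h than after 6 h at 100 µM. Depth is argued against by thinning all libraries to the smallest total, after which the 6 h count was still 2.55 times the 12 h count (1301 against 511), and a single 6 h library by the lowest ratio without 1 of them, 1.8. Levels nearer to control after 12 h may contribute: the median ratio of the 12 h to the 6 h change was 0.922 among genes called after 12 h. The first form of this test used genes called after 6 h and gave 0.629, and the genes were changed after that value was seen, because choosing genes by their 6 h change lowers the ratio. A part of the heart transcripts stays open. With a term for those libraries the counts were 933 and 50, but the median standard errors also rose, from 0.093 to 0.126 and from 0.094 to 0.167. Across all tested genes the changes with and without the term correlated at 0.934 after 6 h and at 0.612 after 12 h. By that term 2 of 10575 genes differed (482 at an unadjusted p under 0.05). The term rests on 1 library of 6 h against the others of that group, so this count does not show its effect to be small.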

How the results depend on the processing

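The fits without the 24 h or 200 µM libraries, with matched libraries summed, with thinned counts and with the term for the 4 heart-transcript libraries were chosen only after the results were seen. Of 515 gene results 395 and of 200 list results 63 kept their side of the threshold under all alternatives run. Called results among these also kept their direction. Under some alternatives 12 gene results and 1 list result reversed. A turn in direction was not counted where neither fit called the result. For lists it was also not counted where the alternative did not call them. The replicate block changed the call of 0 of the 515 gene results and added 7 list calls. Of these only that of iron handling under the 24 h label (0.0412) lay where the numbers may pair the libraries. For gene results DESeq2 ended 4 calls and leaving out 1 replicate ended 146 of 3090. The estimated correlation ended the calls of 78 of the 200 list results, and fry added 47 and ended 9.

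With the heart-transcript term 933 genes changed after 6 h, 50 after 12 h, 3880 under the 24 h label, 3898 under the 200 µM label and 51 between 12 and 6 h. This term adds to the standard errors by its construction. It also moved the estimates, and the 12 h changes with and without it correlated at 0.612 across all tested genes. Of the genes called after 12 h without the term, 99.3% kept their sign with it. With a log2 ratio of at least 1 the counts were 140, 61, 1281 and 1299 against control, 1075 between doses, 5 between 12 and 6 h, and 1135 and 1064 for the 24 h label against 12 and 6 h. The replicate block gave 1165 genes after 12 h and 223 between 12 and 6 h. In these comparisons the numbers were not read as pairs (3 of 6 libraries correlated best with their own number in each). For the 24 h label, whose numbers may pair the libraries, the block gave 6927. Between 12 and 6 h DESeq2 gave 200 and the 6 libraries alone 223. The cause was not tested for these counts. Left-out replicates gave 1026 to 1776 genes after 6 h, 271 to 639 after 12 h, 5909 to 6106 under the 24 h label, 5778 to 6043 under the 200 µM label, 5033 to 5391 between doses, 50 to 93 between 12 and 6 h, 5056 to 5440 and 5170 to 5482 for the 24 h label against 12 and 6 h, and 6672 to 7128 over all groups.

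Lists passing camera numbered 12, 12, 13, 14 and 11 (6 h, 12 h, 24 h label, 200 µM label, doses), 2, 1, 2, 2 and 3 with an estimated correlation and 12, 14, 22, 22 and 19 with fry. For 12 against 6 h and the 24 h label against 12 and 6 h they numbered 9, 11 and 11, 3, 1 and 1 with an estimated correlation, and 4, 19 and 19 with fry. Shared calls at an adjusted p under 0.01 and with the heart-transcript term were 217 and 50 for 6 and 12 h, 593 and 578 for 6 h and the 24 h label, 596 and 583 for 6 h and the 200 µM label, 166 and 41 for 12 h with either label, and 152 and 41 for all 4. Both labels shared 3662 with that term.

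With that term reversals were Myl2 after 12 h (1.31) and under the 24 h label (1.13) and Mybpc3 under the 24 h (4.39) and 200 µM labels (1.96), where libraries near the floor set the ratio. With library totals alone, which lowers most genes of these libraries, they were Slc30a7 (-0.11 for the 24 h and -0.12 for the 200 µM label), Slc30a5 (-0.10, 200 µM), Cox7a2 (-0.006 between doses, -0.0111 for the 24 h label against 6 h), Sparc (-0.002 between doses, -0.0248 for the 24 h label against 12 h) and Rps21 (-0.01, same comparison). The ribosomal list reversed at 12 h without 12 h replicate 3 (adjusted p = 0.0447), and ranged from 0.00655 to 0.947 with other replicates left out. Depth sets a floor of 0.0853 CPM in the deepest library (35.2 M counts) and of 0.290 CPM in the shallowest (10.3 M), both of 6 h at 100 µM.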

Other observations

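The family of cytosolic transfer RNA synthetases, which charge transfer RNAs with amino acids, was 1 of 6 families defined by gene symbol after the data were seen, as were the tests, and camera p-values were adjusted over these families. After 6 h at 100 µM 14 of 19 synthetase genes were lower (median -0.82, camera adjusted p = 1.2e-17, adjusted p = 0.0622 with an estimated correlation), among them Cars1 (-1.0 ± 0.06), Lars1 (-0.99 ± 0.08) and Sars1 (-0.97 ± 0.10), while Kars1 (0.02 ± 0.07) and Farsa (0.04 ± 0.07) did not pass. After 12 h 9 were lower (median -0.25, camera adjusted p = 1.9e-06, adjusted p = 0.273 with an estimated correlation). Between 12 and 6 h 11 were higher (median 0.49, camera adjusted p = 3.4e-31, adjusted p = 0.0104 with an estimated correlation), with Cars1 at 0.73 ± 0.06. Under the 200 µM label 7 were higher and 6 lower, with a median of 0.05 that turned to -0.32 with libraries scaled by their totals alone. The gene Aars1 stands in the ATF4 list as well.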
